A study of Homo sapiens with 4 samples.

How the data were processed

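RNA of A549 cells was measured on 4 one-colour arrays, 1 for each of the groups siCtrl, siPML, vector and WDR4, all at 48 h. Per the labels' protocols, total RNA was extracted with a column kit, amplified and labelled with Cy5. The deposited table holds 1 linear intensity per probe and array. The scanner, the image software, the background correction and any normalization are not given in the sources used here. That the values are linear, background-subtracted intensities was read from the values themselves. They reached the limit of a 16-bit scanner, and 41 probes on siCtrl, 32 on siPML, 42 on vector and 23 on WDR4 were below 0. The upper quartiles of 620, 620, 715 and 709 in the same order differed between the siRNA pair and the plasmid pair of arrays but were close within each pair, so scaling within a pair was not excluded.

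The deposited intensities carried a further structure. Between 10 and 600 units, 96.3% to 100% of the values on each array equalled the mean of 2 whole-number readings, each multiplied by a constant of that array, while at most 0.237% did so after the values were shifted by 0.0137. Whether these readings came from 2 arrays, scans or spots is not given in the sources used here, so each group was counted as 1 replicate. The standard deviation of the log2 ratio of the readings was 0.102 to 0.158 between 300 and 600 units, which gave the technical standard errors in the report. Brighter genes were assigned the same error, which was not measured for them. Dimmer values had a larger standard deviation of that ratio, up to 0.339 on siPML between 10 and 30 units. The number of arrays limits the precision, and the spread between cultures is unknown.

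Probes were named through the platform's gene annotation. Of 31741 probes, 24658 had 1 symbol, 1002 had several and 6081 had none, and only those with 1 symbol were named. Symbols were current for 22404 probes, were updated through the human gene table for 2177 and were kept unmatched for 77. Values below 0 were set to 0, 1 was added and log2 was taken. Each of 18255 genes was represented by its probe with the highest mean over the 4 arrays. Genes were kept when their mean log2 value reached the median of all named genes, 7.81, which left 9128 genes and corresponds to an intensity of 223. The difference of log2 values understates changes of dim genes and of genes at the scanner's limit. At that limit were 64 of the kept genes on at least 1 array and 22 on all 4. No coordinates were used, since no genome build is given in the sources used here.

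With 1 array per group, no test was run and no p-value was computed. Genes at least 2-fold different from their own control were counted. Each of 34 gene lists was described by the median difference of its kept members and the percentile of that median among 10000 random lists of the same size drawn within 20 bins of mean level, for lists with at least 3 members. A list stood apart below percentile 2.5 or above percentile 97.5, as a description of these arrays. The vector array against the siCtrl array was described as well. Both lack the manipulations studied, but they differ in the kind of transfection as well as in the culture.

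The groups, comparisons, gene lists and alternatives were fixed before the data were examined, except where stated. Named genes were PML and WDR4, up to 10 genes in each direction with the largest difference among those at least 2-fold different from both control arrays in the same direction, genes at least 2-fold different in both comparisons, and up to 4 members of each list with the largest absolute difference. Genes in the vector against siCtrl comparison and the further probes and copies of named genes were chosen after their values were seen.

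Alternatives were quantile normalization, centring of each array on the median of all named genes, no filter on dim genes, a stricter filter that kept genes above the upper quartile, the mean over a gene's probes, the other control array, the mean of the 2 control arrays, a threshold of 1.5-fold, and 16 added before log2. Removal of a running median trend along the level over 501 probes, alone or with the 1.5-fold threshold, and leaving out genes at the scanner's limit were added after the data had been seen. Probes with several symbols or none were left out of the comparisons and are described in the closing section.

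The steps were tested on simulated arrays with a noise standard deviation set in advance, which is not an estimate of the real noise. For siPML against siCtrl, in a step of 9128 genes, 98.9% of genes changed by 2 on the log2 scale and 97% of those changed by 1.5 were recovered, with 0.0112% of unchanged genes called. For WDR4 against vector, with 9128 genes, the shares were 100%, 93.8% and 0.0448%. Of simulated lists without a shift, 5% lay outside the central 95% in each. All computations used Python 3.11.15 with numpy 2.4.6, pandas 2.3.3 and matplotlib 3.10.9.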

Results

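Total RNA of A549 cells, an established human lung adenocarcinoma line, was profiled on 4 one-colour expression arrays of 31741 probes each, 48 h after transfection. The groups were a control siRNA (siCtrl), an siRNA against PML (siPML), an empty expression vector (vector) and a WDR4 expression construct (WDR4), with 1 array each. PML is the scaffold protein of PML nuclear bodies, and WDR4 is the partner of METTL1 in the methylation of tRNA and has also been described as a substrate receptor of a CUL4 ubiquitin ligase acting on PML. The design set siPML against siCtrl and WDR4 against vector. The median probe intensity was 106 on siCtrl, 118 on siPML, 121 on vector and 134 on WDR4. There were no replicates, so no difference between arrays was tested, none can be assigned to the treatment rather than to the single culture, and higher and lower refer to the arrays. Differences are given on the log2 scale after adding 1 to the deposited intensity.

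The targeted genes were examined first. All 4 PML probes were lower on siPML than on siCtrl. The brightest read 506 against 853, which was 1.68-fold lower (log2 difference -0.75), and the other 3 differed by -0.28, -0.42 and -1.44. The probe that differed by -1.44 was dim, at 27.0 against 74.9. Of the 2 WDR4 probes, the brighter one read 4708 on WDR4 and 1140 on vector, 4.13-fold higher (2.05). The dimmer one read 890 on WDR4 and 1191 on vector, a difference of -0.42, so the raised WDR4 signal rested on 1 probe. The log2 ratio of the brighter over the dimmer WDR4 probe was 0.08 on siCtrl, -0.24 on siPML and -0.06 on vector, against 2.40 on WDR4. On siPML, both WDR4 probes were lower than on siCtrl, by differences of -0.89 and -0.57. The brightest PML probe read 3840 on vector, 4.50-fold above siCtrl, and 5015 on WDR4. The type I interferon list described below moved the same way, with medians of -0.96 on siPML and 3.89 on vector, both against siCtrl. The lower PML reading on siPML therefore could not be assigned to the siRNA alone. The differences of WDR4 from vector on the 4 PML probes, from brightest to dimmest, were 0.38, 0.03, 0.30 and -0.14. A technical standard error of the log2 difference, estimated from paired readings recovered from the deposited values, was 0.11 for siPML against siCtrl and 0.08 for WDR4 against vector, and it leaves out all variation between cultures.

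**Figure D1:**
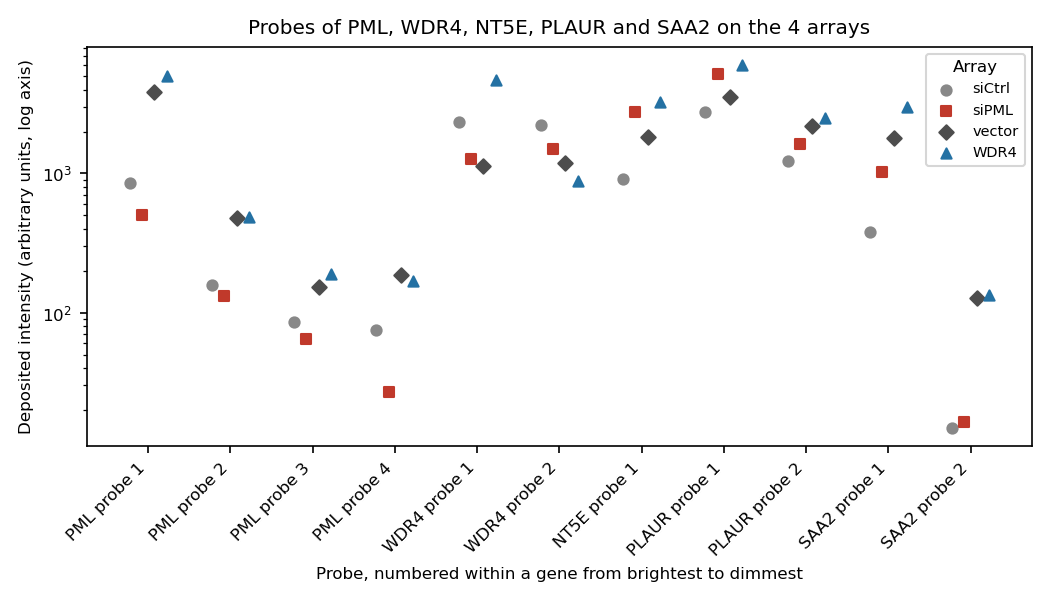
Deposited intensity (arbitrary units, log axis) of each probe of PML, WDR4, NT5E, PLAUR and SAA2, with 1 point per array and probes numbered within a gene from brightest to dimmest. The brighter WDR4 probe reads 4708 on the WDR4 array and 1140 on the vector array, while the dimmer one reads 890 and 1191.

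Interferon-induced genes were lower and genes of hypoxia and glycolysis were higher on siPML than on siCtrl. MX1, an interferon-induced antiviral GTPase, read 229 on siCtrl and 4.07 on siPML, close to the bottom of the scale. IFI44L read 495 and 38.7 (-3.64), and IFI27 read 681 and 109 (-2.63). HK2, the hexokinase that starts glycolysis, read 919 and 3681, which was 4.01-fold higher, and the aldolase ALDOC read 3207 and 12460 (1.96). Among 9128 genes above the intensity filter, 210 were at least 2-fold higher and 390 at least 2-fold lower on siPML, and 162 and 499 when each array was centred on its own median. Without the filter on dim genes the balance turned, with 734 higher and 578 lower. The lower quartile of probe intensities was 23.5 on siPML against 19.4 on siCtrl.

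Among genes also at least 2-fold above the vector array, the highest on siPML was CLEC2B, which encodes a C-type lectin, at 37793 against 3614, or 10.5-fold higher (3.39). PPP1R3C, a glycogen-targeting subunit of protein phosphatase 1, followed with a log2 difference of 2.29, TNFSF9, the ligand of the T cell receptor 4-1BB, with 2.16, and the ubiquitin ligase MARCHF4 with 2.12. TCN1, a vitamin B12 carrier, was higher by 2.01, LONRF1 by 1.89, A1CF by 1.81 and the glucose transporter SLC2A3 by 1.67. Among the lower genes, LAPTM4A, a lysosomal membrane protein, read 1758 against 14036 (-3.00), and the cytokine LTB differed by -2.82. The lipid droplet protein CIDEC differed by -2.69, EMC8 of the endoplasmic reticulum membrane complex by -2.64, the Polycomb-associated protein PHF19 by -2.60, and the transporters SLC7A7 and SLC46A3 by -2.40 and -2.37. These genes were also at least 2-fold different from the vector array in the same direction, as were 51 of the 210 higher and 263 of the 390 lower genes.

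Gene lists fixed before the data were examined were described by their median difference and its percentile among 10000 random lists. The random lists were of like size and of like mean intensity over all arrays. The type I interferon list lay at the bottom in siPML against siCtrl, with a median of -0.96 (percentile 0). Of its 26 measured members, 22 were below 0 and 13 were at least 2-fold lower, including IFIT1 (-2.35). On both siCtrl and siPML, 10 of the 26, among them OAS2 and XAF1, read below 223, the intensity of the filter, which they passed through their level on the other arrays. The random lists matched the mean over all arrays, and for these 26 genes vector lay above siCtrl by a median of 3.89. Percentile 0 is thus not relative to lists of like intensity on siCtrl and siPML themselves. E2F and DNA replication genes had a median of -0.60 (percentile 0), with 20 of 22 members below 0, among them thymidine kinase TK1 (-1.57), GINS1 (-1.44) and the ribonucleotide reductase subunit RRM2 (-1.28). Mitosis genes had a median of -0.55 (percentile 0.01), with 22 of 23 members below 0, among them the proliferation marker MKI67 (-1.98), TOP2A (-1.71) and KIF20A (-1.32). Against the vector array both lists turned, to medians of 0.44 for E2F and 0.41 for mitosis genes.

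The hypoxia and glycolysis list of 21 genes had a median of 0.72 in siPML against siCtrl (percentile 100), and 7 genes were at least 2-fold higher. All 20 of its genes that were not at the scanner's limit on both arrays were above 0. P4HA1, a collagen prolyl hydroxylase, was higher by 1.43. Cholesterol synthesis genes had a median of 0.51 (percentile 99.99), with HMGCS1 at 1.24, INSIG1 at 1.19 and SQLE at 0.97 and 10 of 14 members above 0. p53 targets had a median of 0.34 (percentile 99.95), with 19 of 24 members above 0. The pro-apoptotic BBC3 (2.41) and the antiproliferative BTG2 (1.66) stood highest, while CCNG1 differed by -0.90. The 9 core histone genes had a median of 0.52 (percentile 99.8), with H1-2 at 0.96, and all 8 that were not at the scanner's limit were above 0. Immediate early genes had a median of 0.42 (percentile 99.9), with 10 of 12 members above 0 and the phosphatase gene DUSP5 at 1.25. Their median ranged from 0.32 to 0.75 over the 8 alternatives that kept the own control. The 20 cytosolic ribosomal protein genes had a median of 0.28 (percentile 99.9). Of them, 4 were at the scanner's limit on both arrays, 15 of the other 16 were above 0, and RPL23 differed by -0.66. Extracellular proteases had a median of 0.24 (percentile 98.3) with members going both ways, as PLAT, the tissue plasminogen activator, was higher by 1.30 and the protease inhibitor TIMP2 differed by -2.35. The position of this last list was lost under 3 of 8 alternative settings. Against the vector array, the medians turned to -0.25 for p53 targets, -0.87 for histones, -0.72 for immediate early genes and -0.31 for proteases.

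NT5E (the ectonucleotidase CD73), PLAUR (the urokinase receptor) and SAA2 (a serum amyloid protein) were followed up in the published study. That choice came from these profiles, so their direction here is not independent evidence. On siPML, NT5E read 2773 against 910 on siCtrl (1.61), the brighter PLAUR probe 5209 against 2763 (0.91) and the brighter SAA2 probe 1016 against 378 (1.42). Their median of 1.42, the value of SAA2, lay at percentile 100, and it was 0.78 with the mean over a gene's probes. Against the vector array the median was 0.56 (percentile 95.7), and SAA2 turned to -0.83. The dimmer PLAUR probe differed by 0.40, and the dimmer SAA2 probe, near background on siCtrl at 14.9, by 0.13. SAA2 is uncertain because its near-identical copy SAA1, which differed by 0.77, can share probe signal.

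The remaining lists did not stand apart in siPML against siCtrl. PML nuclear body components had a median of -0.29 (percentile 5), with the kinase HIPK2 at -1.96. CUL4 ligase subunits also had a median of -0.29 (percentile 3.59). Macrophage markers had a median of -0.41 (percentile 7.75), heat shock proteins -0.20 (11.9), mitochondrial respiratory chain genes -0.15 (12.2), NF-kB targets -0.14 (12.4), acute phase proteins -0.10 (29.1), tRNA modification genes -0.09 (22.7) and alveolar markers -0.07 (30). Medians above 0 were found for mesenchymal markers at 0.19 (percentile 92.7), TGF-beta targets at 0.19 (92.5), MHC class I presentation at 0.18 (91.4), purine signalling at 0.17 (80.9) and cell-matrix adhesion at 0.16 (95.2). So were those of immune checkpoint ligands and suppressive factors at 0.15 (88.4), the unfolded protein response at 0.15 (95.4), epithelial junction markers at 0.11 (79.0) and housekeeping genes at 0.10 (81.8). Of the 13 housekeeping genes, 7 were above and 6 below 0, and 3 were at least 2-fold lower, against 4.27% of all named genes. The median of NRF2 targets fell on a gene at the scanner's limit, and over the 19 members not at that limit on both arrays it was -0.09, with 9 above and 10 below 0. Lists for T cells, endothelium, fibroblasts and embryonic kidney lines held fewer than 3 measured members and were given no median in either comparison. Apart from the list the study chose, 7 lists stood above and 3 below their random lists, where 1.45 of 29 would be expected of randomly drawn genes. Genes of a list can vary together, so 1.45 is not the number expected between cultures. Between the vector and siCtrl arrays, both controls, 11 lists stood above and 3 below.

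**Figure D2:**
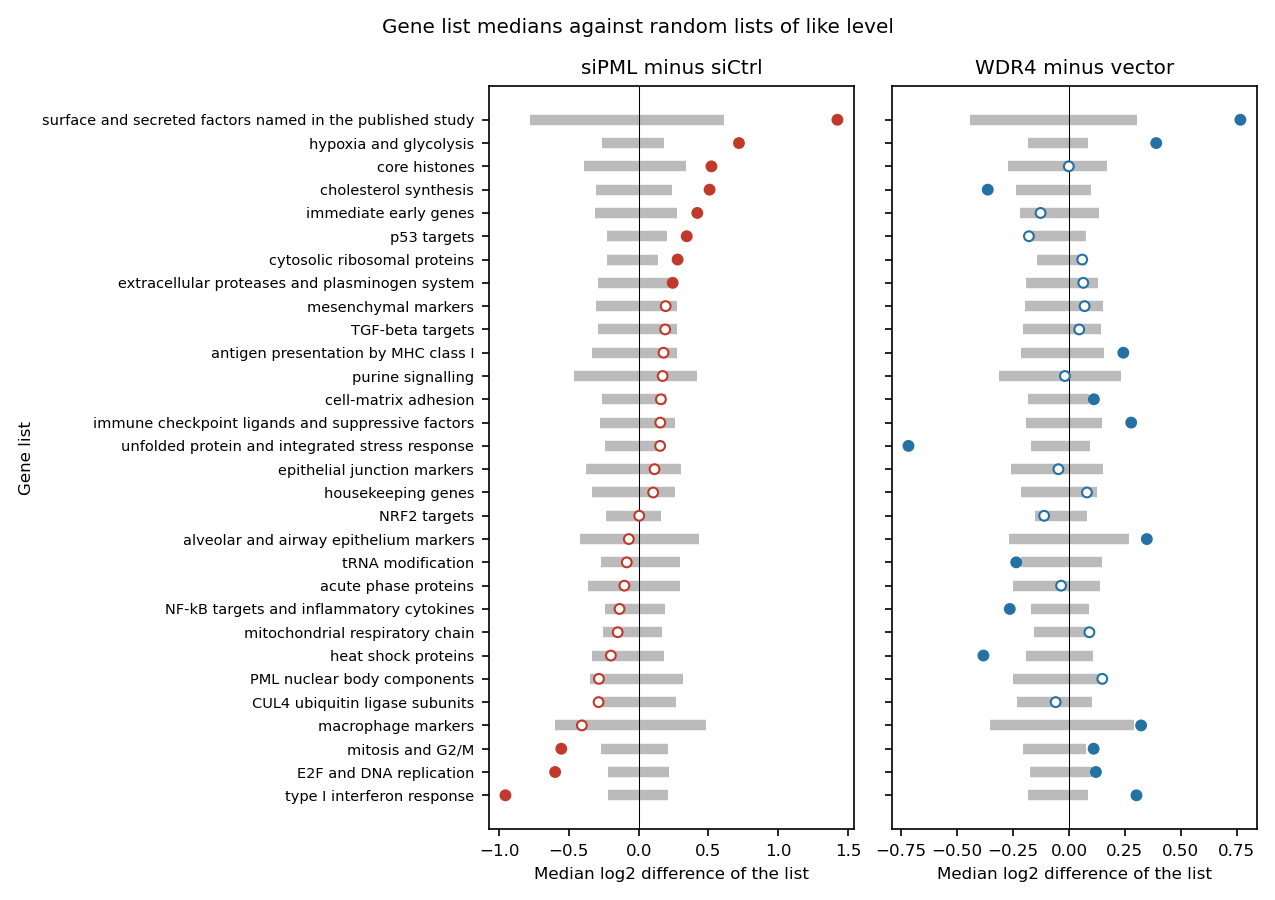
Median log2 difference of each of 30 gene lists in siPML minus siCtrl and in WDR4 minus vector, on axes of different range, with grey bars for the central 95% of 10000 random lists and filled points for lists outside those bars. The interferon list lies at -0.96 in the siPML comparison and at 0.30 in the WDR4 comparison, and the unfolded protein response list at 0.15 and -0.72.

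Genes of the unfolded protein response were lower, and interferon and hypoxia genes were higher, on WDR4 than on vector. DNAJB9, a chaperone partner of the endoplasmic reticulum, read 1540 against 6617 (-2.10), HSPA5, its main chaperone there, 367 against 1206 (-1.71), and CRELD2 differed by -1.63. IFIT2, an interferon-induced RNA-binding protein, read 5051 against 2117 (1.25), and the hypoxia-induced ANGPTL4 was higher by 1.42. Differences were smaller than for siPML, as 33 of 9128 genes were at least 2-fold higher and 26 at least 2-fold lower, or 27 and 38 when each array was centred on its own median and 404 and 81 without the filter. The central 95% of genes spanned -0.63 to 0.62, against -1.19 to 0.97 in siPML against siCtrl.

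Besides WDR4 itself, 6 genes were at least 2-fold higher on WDR4 than on both control arrays. These were the Golgi protein TMEM165 (1.54), the pyruvate kinase PKLR (1.39), the kinase LMTK2 (1.37), IFIT2, the ubiquitin ligase TRIM25 (1.25), which acts in RNA sensing, and the ribonuclease PNPT1 (1.01). The 4 genes lower than both controls were the replication licensing factor CDC6 at 1062 against 3251 (-1.61), the kinase DYRK1B (-1.44), the disulfide isomerase AGR2 (-1.38) and the enzyme GMPPB (-1.22).

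The unfolded protein and integrated stress response list had a median of -0.72 (percentile 0) in WDR4 against vector, with 21 of 23 members below 0 and 7 at least 2-fold lower. HERPUD1, which acts in degradation of misfolded proteins, read 16546 against 65555, the scanner's limit on vector, so its difference of -1.99 is a lower bound on the size. The vector array itself was high for this list, with a median of 1.07 over siCtrl, and the WDR4 array lay above siCtrl by a median of 0.34. Heat shock proteins had a median of -0.38 (percentile 0.01), with HSPA1A at -1.22, though its near-identical copy HSPA1B (-0.78) can share probe signal. Cholesterol synthesis genes had a median of -0.36 (percentile 0.03), with 13 of 14 below 0 and the reductase DHCR7 at -0.71. NF-kB targets had a median of -0.26 (percentile 0.01), with 13 of the 20 genes not at the scanner's limit on both arrays below 0, NFKB1 at -0.67 and CXCL2 at -0.66, while BCL3 was higher by 0.92. This position was lost when only genes above the upper quartile of intensity were kept, and the list lay above siCtrl on WDR4 by a median of 1.23. tRNA modification genes had a median of -0.24 (percentile 1.285), with 11 of 17 below 0, including METTL1 (-0.57) and TRMT61A (-0.79) and with the overexpressed WDR4 among the 17. That position was lost under 3 of 8 alternative settings, and the median turned to 0.11 when only genes above the upper quartile were kept.

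On the higher side in WDR4 against vector, 25 of 26 interferon genes were above 0, with a median of 0.30 (percentile 100). SAMD9 was higher by 0.84 and IFIH1, a sensor of double-stranded RNA, by 0.76. MHC class I presentation genes had a median of 0.24 (percentile 99.5), with 8 of 10 above 0 and the immunoproteasome subunit PSMB9 at 0.35. Hypoxia and glycolysis genes had a median of 0.39 (percentile 100), with 16 of the 20 genes not at the scanner's limit on both arrays above 0, the matrix enzyme LOX at 0.70, ADM at 0.69 and NDRG1 at 0.67. Against siCtrl their median on WDR4 was -0.12. Among immune checkpoint ligands and suppressive factors, the ligand CD276 (B7-H3) was higher by 0.61 and the enzyme IDO1 by 0.46. This list, which also holds NT5E, had a median of 0.28 (percentile 99.95), with 10 of 14 above 0. Its median ranged from 0.17 to 0.32 over the 8 alternatives that kept the own control. Cell-matrix adhesion genes had a median of 0.11 (percentile 98.8), with 14 of 20 above 0 and the integrins ITGB6 at 1.13, ITGAV at 0.80 and ITGA6 at 0.71. This position was lost under 1 of 8 alternative settings. All 7 alveolar epithelium markers were above 0, with a median of 0.35 (percentile 99.4) and MUC1 at 0.65. Of 4 macrophage markers, 3 were above 0, with a median of 0.32 (percentile 98.3), AIF1 at 0.44 and CD14 at -0.52. The positions of both these lists were lost without the filter on dim genes, and against siCtrl their medians turned to -0.037 and -0.17. E2F genes had a median of 0.12 (percentile 98.6) with 15 of 22 above 0 and TYMS at 0.55, and mitosis genes had a median of 0.11 (percentile 99.3) with 17 of 23 above 0 and DLGAP5 at 0.44. The positions of the E2F and mitosis lists were lost under 3 and 2 of 8 alternative settings, and against siCtrl their medians turned to -0.80 and -0.89.

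The study's own factors were higher on WDR4 too, with NT5E at 3285 against 1828 (0.85), the brighter PLAUR probe at 6000 against 3527 (0.77) and the brighter SAA2 probe at 3002 against 1809 (0.73). Their median of 0.77 lay at percentile 99.995, and it ranged from 0.48 to 0.86 over the 8 alternatives that kept the own control. The same limit on independence holds. The dimmer PLAUR probe differed by 0.19 and the dimmer SAA2 probe by 0.07, while SAA1 differed by 0.51. On the vector array, these 3 genes already lay above siCtrl, with a median of 1.01 (percentile 97.7).

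The other lists did not stand apart in WDR4 against vector. PML nuclear body components had a median of 0.15 (percentile 96.95), mitochondrial respiratory chain genes 0.09 (97.3), housekeeping genes 0.08 (93.4), mesenchymal markers 0.07 (85.9), extracellular proteases 0.06 (90.2), ribosomal proteins 0.06 (95.8) and TGF-beta targets 0.05 (83.1). Medians below 0 were found for p53 targets at -0.18 (percentile 3.02), immediate early genes at -0.13 (19.7), NRF2 targets at -0.11 (10.4), CUL4 ligase subunits at -0.06 (55.5), epithelial junction markers at -0.05 (56.0), acute phase proteins at -0.04 (63.4), and purine signalling at -0.02 (60.8). The median of core histones fell on a gene at the scanner's limit, and of the 8 other members 4 were above and 4 below 0. Under at least 1 other scaling between arrays, the sign turned for the mesenchymal, protease, ribosomal, TGF-beta, CUL4, acute phase and purine lists. Apart from the list the study chose, 9 lists stood above and 5 below their random lists, against 11 and 3 for the vector array against siCtrl.

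**Figure D3:**
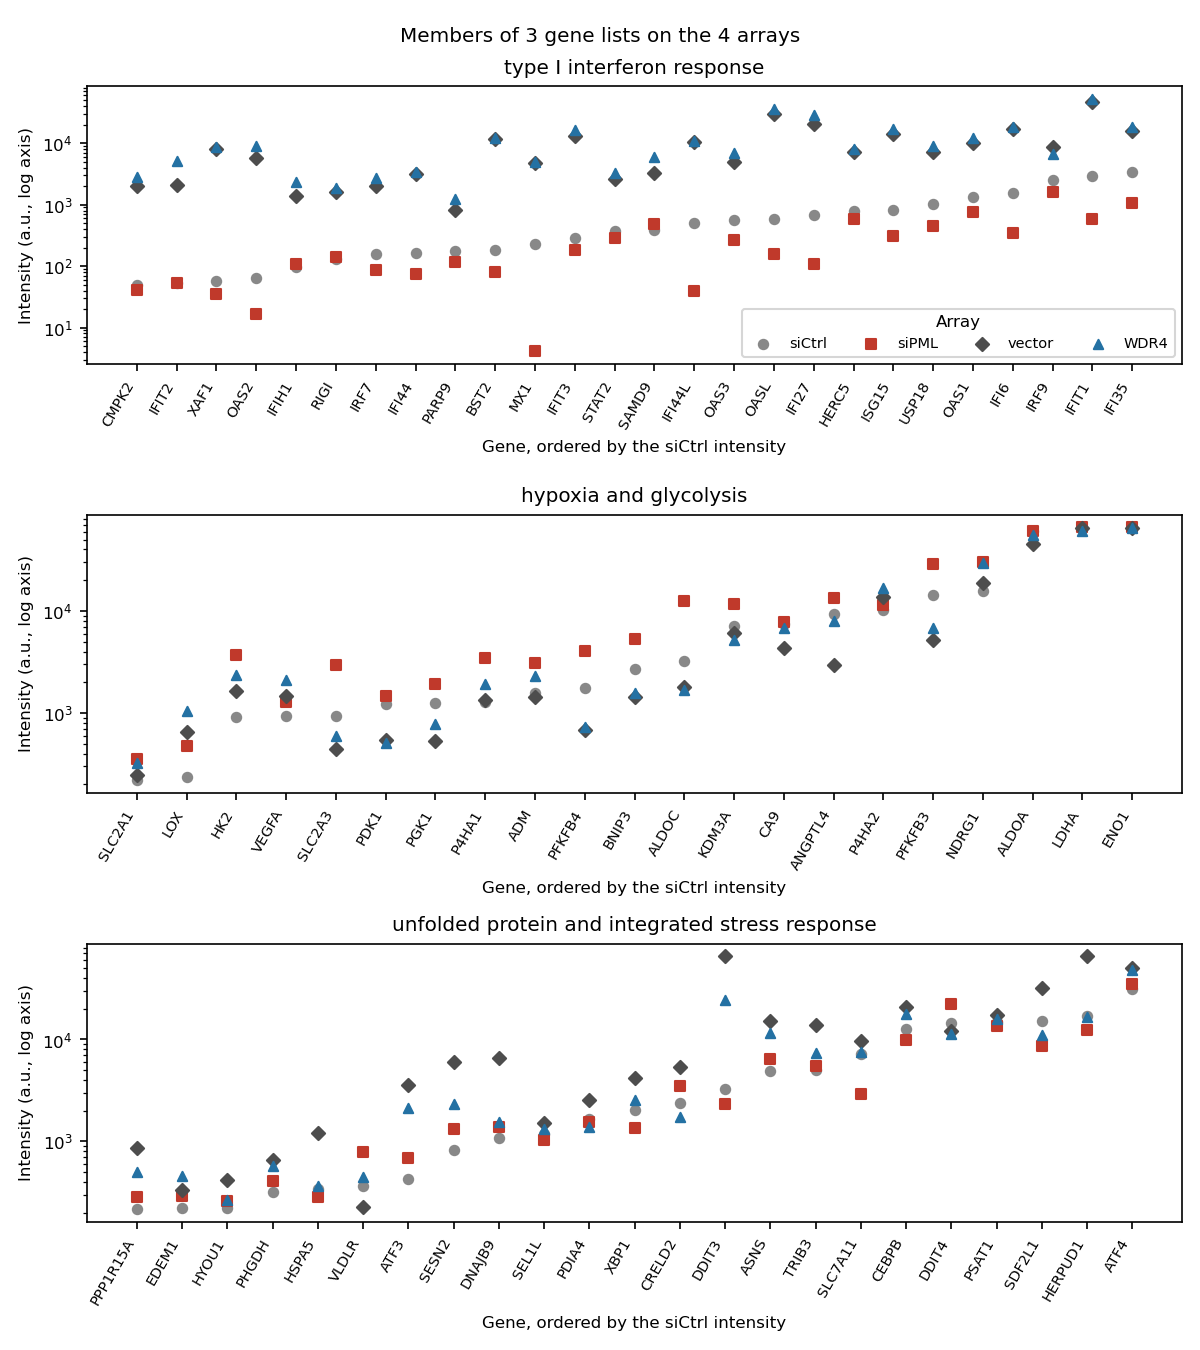
Deposited intensity (arbitrary units, log axis) of each measured member of the interferon, hypoxia and unfolded protein response lists, with genes ordered by their siCtrl intensity and 1 point per array. MX1 lies at 229 on siCtrl, 4.07 on siPML and 4838 on vector, and HSPA5 at 343 on siCtrl, 1206 on vector and 367 on WDR4.

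The comparisons of siPML and WDR4 share no array, and they had 3 genes at least 2-fold lower in common, against 1.11 expected of independent lists. These were ERO1B, an oxidase of the endoplasmic reticulum (-1.34 on siPML and -1.21 on WDR4, where it turned to 0.22 against siCtrl), the ephrin EFNA1 (-1.54 and -1.15) and HSPA1A (-1.11 and -1.22). No gene was at least 2-fold higher in both, against 0.759 expected, while 56 were without the filter on dim genes, against 16.2 expected. At 1.5-fold, 70 genes were higher in both against 28.5 expected, and 35 were lower in both against 39.2 expected. The 70 genes included NT5E, PLAUR and SAA2 and, among members of the lists above, ADM, LOX, NDRG1, ITGA6, ITGAV, CD276 and VLDLR, a member of the unfolded protein response list that went against that list's direction on WDR4. Across the 9128 genes, which are not independent replicates, the differences of both comparisons had a Pearson r of 0.09 and a Spearman rho of 0.09. The r was 0.18 without the filter, -0.20 against the mean of both controls and -0.65 with the controls exchanged. In the last 2 settings, the difference between the controls enters the comparisons with opposite signs. That pushes r down by construction, so these 2 values say nothing about agreement of the comparisons.

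The vector and siCtrl arrays, both controls, differed from each other more than either treated array differed from its own control. Interferon genes were far higher on vector, where XAF1 read 8098 against 58.0 on siCtrl (7.10) and OAS2 5772 against 63.5 (6.48). All 26 interferon genes were at least 2-fold higher, with a median of 3.89 (percentile 100). Of these, 10, XAF1 and OAS2 among them, read below 223 on both siRNA arrays and passed the filter only through vector and WDR4. For those 10 the direction was largely fixed by the filter. NF-kB targets had a median of 1.77 and MHC class I presentation genes 1.12, both at percentile 100, with IL1A at 4.20 and HLA-F at 3.86. Mitosis genes had a median of -1.05 and E2F genes -0.95, both at percentile 0. The fibrinogen chains FGB (-4.39) and FGG (-3.20) were the lowest genes. In total, 861 genes were at least 2-fold higher and 287 lower on vector, and the standard deviation of the differences was 0.73, against 0.54 for siPML and 0.32 for WDR4 and their own controls. The kind of transfection and the control culture were not separable in this comparison.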

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

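In this part, the tests of a response to the control siRNA, of slowed growth and of the construct's extent were chosen only after the result was seen. Probes without a single gene symbol were outside the comparisons, and 36 of the 1731 bright enough for the filter were at least 2-fold higher on siPML than on siCtrl. On WDR4, 9 of them were at least 2-fold higher than on vector. These were 2.08% and 0.520% of such probes, against 2.30% and 0.362% of the named genes. At least 2-fold lower were 70 on siPML and 7 on WDR4, or 4.04% and 0.404%, against 4.27% and 0.285% of the named genes.

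Interferon genes were lower on siPML than on siCtrl. With the level trend removed the list stayed at percentile 0, but random lists matched on level could hardly let this percentile move. Over the 8 alternatives that kept the own control, trend removal among them, the median was -1.19 to -0.86. A trend along the mean level thus left the shift in place. That level was the mean over all arrays, and XAF1 read 58.0 on siCtrl, 35.4 on siPML and 8098 on vector. Quantile normalization, which rescales each array along its own levels, was among the 8 alternatives. The lower quartile, median and upper quartile of probe intensity were 19.4, 106 and 620 on siCtrl and 23.5, 118 and 620 on siPML. Scaling along an array's own level would thus not lower genes in that range on siPML, yet 22 of the 26 were lower. These values argue against level-dependent scaling for this list, though 10 of the 26 were dim on both siRNA arrays. A candidate explanation is an interferon response raised by the control siRNA and not by the siPML siRNA. Across the 26 genes, the differences of vector and of siPML from siCtrl had a Spearman rho of -0.25, but both subtract the same siCtrl array, which by itself pushes rho upward, and 10 of the genes were dim on both siRNA arrays, so this value decides nothing. Without an untransfected array the explanation cannot be told apart from an effect of PML loss on interferon signalling, an untested hypothesis. Other effects of the siPML siRNA and differences between the single cultures were not tested either.

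Hypoxia and glycolysis genes were higher on both treated arrays than on their own controls. With the trend removed the lower of both percentiles was 100. The random lists were already matched on level, so a level trend could hardly move these percentiles. Over the 8 alternatives that kept the own control, trend removal among them, the median was 0.62 to 0.95 on siPML. On WDR4 it was 0.31 to 0.44. A trend along the mean level thus left both shifts in place. A culture with exhausted medium and slowed growth is a candidate explanation for siPML, where the mitosis list lay at percentile 0.01 against siCtrl. That list turned to 0.41 against vector and to 0.030 against the mean of both controls, so slowed growth was not decided for siPML. For WDR4 the mitosis list lay at percentile 99.3 against vector, opposite to slowed growth. This position was lost under quantile normalization and with the trend removed. The median of the list still stayed above 0, at 0.031 to 0.13, over the 8 alternatives that kept the own control. Against siCtrl the list turned to -0.89 and against the mean of both controls to -0.40, both at percentile 0. The hypoxia list on WDR4 turned to -0.12 against siCtrl. The vector array is the own control over which the hypoxia list was higher on WDR4. Against it, the mitosis values argue against slowed growth, for these single arrays. The values against siCtrl also hold the difference between the controls, which had a median of -1.05 for the mitosis list. Effects of the manipulations on these genes stay open for both arrays.

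The 2 WDR4 probes disagreed on the WDR4 array alone. If the dimmer probe did not measure WDR4 transcripts, its ratio to the brighter one would range as widely over the other 3 arrays as that of random probe pairs, but the range of 0.32 lay at percentile 8.27 of such pairs, whose median range was 0.94. A construct that lacks the target of the dimmer probe is a candidate explanation for the log2 ratio of 2.40 on the WDR4 array, against -0.24 to 0.08 on the others. Probe positions and the construct's sequence were not used here, so this cannot be told.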

How the results depend on the processing

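The level trend removal, alone or with the 1.5-fold threshold, and the omission of genes at the scanner's limit were chosen only after the data had been seen, and the cause of the changes below was not tested unless stated. No paired analysis was possible because each group held 1 array, and for the same reason no replicate could be left out. Adding 16 before log2, centring each array and leaving out genes at the scanner's limit kept all counts within 1.5 times. Centring moved the array medians of all named genes, which were 7.62 on siCtrl, 7.72 on siPML, 7.87 on vector and 7.95 on WDR4. Over the 8 alternatives that kept the own control, 10 of the 11 lists that stood apart for siPML did so in all. For WDR4, the NF-kB, E2F, mitosis, adhesion, tRNA modification, alveolar and macrophage lists lost their position in at least 1.

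With quantile normalization, the WDR4 gene was higher by 2.18 on WDR4, 2 genes were at least 2-fold higher in both comparisons and r was 0.074. Without a filter, which admits dim genes, 734 genes were higher on siPML, 404 higher and 81 lower on WDR4, 56 higher and 10 lower in both, r was 0.18, and 2230 genes differed between the controls. By their lower quartiles, dim probes read higher on both treated arrays than on their own controls. With only genes above the upper quartile, which are fewer, the counts were 68 higher and 198 lower on siPML, 11 and 14 on WDR4, and 489 between the controls, and the tRNA modification list turned to 0.11 on WDR4. With the mean over probes, which averages the disagreeing WDR4 probes, the WDR4 gene was higher by 0.81, and 1 gene was higher in both. With the mean over probes, fewer differences of named genes were at least 2-fold in size than under any other setting that kept the threshold. Their sign was not counted. Most of these genes had been chosen as at least 2-fold different from both controls. That they held against the other control or the mean of both was thus largely fixed by that choice. At 1.5-fold, a lower threshold, the counts were 922 and 1174 on siPML, 282 and 305 on WDR4, and 70 and 35 in both. With the level trend removed, 1 gene was higher in both and r was 0.079, and with the 1.5-fold threshold as well the counts were 879 and 1189, 299 and 293, and 75 and 29.

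Exchanging the control arrays changed most, by the size of the difference between the controls. siPML against vector gave 338 genes higher and 1154 lower and PML at -2.92. WDR4 against siCtrl gave 742 and 284 and WDR4 at 1.00. Then 5 genes were higher in both, and r reversed to -0.65. The difference between the controls then enters the comparisons with opposite signs, which pushes r down by construction. For siPML the reversed medians were p53 targets -0.25, E2F 0.44, mitosis 0.41, proteases -0.31, histones -0.87 and immediate early genes -0.72, and SAA2 turned to -0.83. For WDR4 they were NF-kB 1.23, E2F -0.80, mitosis -0.89, hypoxia -0.12, unfolded protein response 0.34, alveolar markers -0.037 and macrophage markers -0.17, and ERO1B turned to 0.22. Against the mean of both controls, 605 genes were lower on siPML with PML at -1.84, and 201 were higher on WDR4 with WDR4 at 1.52. Then 11 were higher in both and r was -0.20, again with the control difference entering with opposite signs. For siPML, mitosis turned to 0.030, proteases to -0.029, histones to -0.23 and immediate early genes to -0.23. For WDR4, NF-kB turned to 0.52, E2F to -0.35 and mitosis to -0.40. Signal over background limits dim genes, and because the filter used the mean over all 4 arrays, genes dim on both arrays of a comparison could pass it, as 10 of 26 interferon genes did for siPML.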

Other observations

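The genes in this part were chosen after their values were seen, and no test was run on them. They are single genes and stand for no group. In siPML against siCtrl, HIF1A, the oxygen-regulated transcription factor, differed by -1.99 and -0.78 on its 2 probes, although the hypoxia list was higher. STAT3, a transcription factor of cytokine signalling, differed by -1.78 and -1.52 on 2 probes. HIPK2, a kinase of PML nuclear bodies, differed by -1.96, -1.93 and -1.91 on 3 probes, and it lay above vector by 0.61 on WDR4. The E-cadherin gene CDH1 differed by -1.95 and HPRT1, a purine salvage enzyme used as a reference gene, by -2.02. The GTPase gene CDC42 differed by -2.37 on its brighter probe and by 0.78 on the other, so its probes disagreed.

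In WDR4 against vector, FICD, which modifies the chaperone HSPA5, read 297 against 1339 (-2.17), and the secreted stress factor MANF read 712 against 2000.5 (-1.49). On siCtrl, FICD read 271 and MANF 856. DDIT3, the stress transcription factor CHOP, read 24436 on WDR4, 65554 on vector, at the scanner's limit, and 3249 on siCtrl. EGR1, an immediate early transcription factor, read 883 on WDR4, 3797 on vector and 353 on siCtrl. HEXA, a lysosomal hexosaminidase, was higher by 1.70 on WDR4 than on vector and by 0.78 on siPML than on siCtrl.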
